A study of Mus musculus with 6 samples.

How the data were processed

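RNA from brain of mice given vehicle or TMAO was sequenced in 3 libraries per group, on an Illumina NovaSeq instrument per the labels' protocols. The extract protocol in the labels speaks of pooled RNA in a template sentence with unfilled fields, so whether a library held RNA of several animals is not given in the sources used here. Reads were trimmed with cutadapt 1.9, per the submitters' processing notes, which also name the mouse build mm9. The aligner, the quantifier, the gene annotation and the test behind the deposited p-values are not given in the sources used here. Of the deposited gene IDs, 99.6% are in the GENCODE M21 annotation of GRCm38, as are 99.2% of the transcript IDs, so the coordinates printed are those of GRCm38 and were found by gene ID.

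The authors deposited 2 tables with the same values in a different order, each with FPKM of 36758 genes in the 6 libraries, per the file headers. The deposited tables also hold the authors' ratio (fold) of the mean FPKM of TMAO over vehicle, its log2, and the authors' p-value and q-value per gene. The deposited fold equals the ratio of group means, and the deposited q-value equals a Benjamini-Hochberg adjustment over the 34778 genes with a value above 0. Libraries were matched to groups through the library names in the labels. All value columns were matched.

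The tables give FPKM and no read counts, so tests for counts were not run and depth was judged from the smallest steps of low values in genes with a single transcript. The most common step put the relative depth of the libraries between 0.970 and 1.02, but only 11.7% to 14.3% of the low values lay within 2% of a whole step, so reads could not be recovered. The precision of a value is therefore given by the spread between libraries alone.

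FPKM were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept, which left 14206 genes, and were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend and robust estimation), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design files written before the data were examined allowed a count test or this test, depending on the unit found. 40 gene lists, 15 of them of cell type markers, were fixed before the data were examined. Lists with at least 5 measured members, 36 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. A symbol with several gene IDs was represented by the ID with the highest mean FPKM. Single values and list sums were compared with exact two-sided permutation tests, whose p cannot go under 0.1 with 3 against 3 libraries. The heat shock, immediate early, ribosomal, mitochondrially encoded and sex lists were fixed as checks of sample handling and library quality. The Y-linked gene Ddx3y was at 13.5 to 25.7 FPKM and Xist at 0.0397 to 0.141 FPKM in all 6 libraries.

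Named genes followed a rule fixed before the data were examined. It took the 8 inflammasome and m6A genes of the study, up to 4 members with the smallest p from each list described, and genes past the threshold. As none passed, it took the 5 genes with the smallest p in each direction among those above the median of mean expression, with an assigned symbol and with groups that did not overlap. Markers printed as levels of cell types were chosen from the fixed lists after their values were seen.

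The gene test and the list test were tested on simulated data made from the mean and spread of the 14206 genes, with 200 genes changed. The oligodendrocyte markers were lowered together as well. For TMAO against vehicle with the spread of all 6 libraries the gene test called 44.8%, 88.1% and 92.4% of genes changed 2-fold, 4-fold and 8-fold, and it called 8 of the unchanged genes. With the spread without vehicle replicate 1 it called 79.1%, 89.6% and 95.5%. In both, camera with the preset correlation called the lowered list and 0 other lists. Each gene was drawn independently, with no correlation between genes and no library set apart, so these shares may not hold for the real libraries. Alternatives covered normalization, the pseudocount, the low-expression filter, the variance trend, a replicate block, thresholds and leaving out each library. Fits without robust estimation, with array weights and without mitochondrially encoded genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.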

Results

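Gene expression was measured by RNA sequencing in 6 libraries of mouse brain RNA that the labels assign to microglia, the resident immune cells of the brain. 3 libraries came from C57BL/6J mice given water as vehicle, and 3 came from mice given 0.12% trimethylamine N-oxide (TMAO) daily over 16 weeks. TMAO is made in the liver from trimethylamine, which gut bacteria release from choline and carnitine. The title of the series names the NLRP3 inflammasome of microglia, the RNA demethylase FTO and the RNA-binding protein IGF2BP2, and injury in stroke. The sample labels describe the diet and no stroke surgery. Values are fragments scaled by gene length and library size (FPKM) for 36758 genes, of which 27368 to 28032 were above 0 in a library. Read counts were not used here, and the total FPKM per library ran from 305701 to 326977. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

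All 6 libraries held abundant RNA of neurons, astrocytes and oligodendrocytes. The synaptic gene Snap25 ran from 61.0 to 281 FPKM and the astrocyte glutamate transporter Slc1a2 from 152 to 210 FPKM. The myelin gene Mbp ran from 139 to 330 FPKM. The microglial genes P2ry12 and Tmem119 lay between 2.47 and 6.29 FPKM and between 3.21 and 6.81 FPKM. Summed over its list, the 10 microglia markers gave 140 to 394 FPKM per library, against 566 to 1810 FPKM for the 15 neuron markers. Vehicle replicate 1 stood apart from the other 5 libraries. Across genes, which are not independent replicates, its log2 values correlated with the others at 0.804 to 0.896, while the other 5 correlated with each other at 0.959 to 0.986. Its neuron markers summed to 566 FPKM against 1482 to 1810 FPKM in the other 5, and its border macrophage markers were 8.39 times the mean of the other 5. On the axis of largest variation between libraries (79.2% of the variance), vehicle replicates 1, 2 and 3 lay at -80.7, -6.61 and 13.6. The TMAO libraries lay at 19.8 to 28.8. Vehicle replicate 2 was thus shifted the same way, less strongly. Its neutrophil markers summed to 86.3 FPKM, against 17.6 to 37.0 FPKM in vehicle replicate 3 and TMAO. Values without vehicle replicate 1 still include this shift. The share of FPKM from mitochondrially encoded genes was 26.3% in vehicle replicate 1 and 29.1% to 32.0% elsewhere.

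The first comparison asked which genes differed between TMAO and vehicle. No gene passed, so the genes named here did not pass the test over all genes. They have the smallest p in each direction among genes with an assigned symbol, a mean expression above the median and groups without overlap. Lower in TMAO were the adult beta globin gene Hbb-bt, at 59.5 ± 31.4 FPKM in vehicle and 8.71 ± 2.44 FPKM in TMAO (SD, n = 3 each; log2 difference -2.55, SE 0.382), and Nkain1 (-0.88), Wscd1 (-0.77), the nuclear import gene Kpna2 (-0.78) and Medag (-0.71). Hbb-bt has near-identical paralogs, so its share of their reads is uncertain. Higher in TMAO were Btbd3, at 18.9 ± 2.54 FPKM in vehicle and 33.9 ± 2.58 FPKM in TMAO (log2 difference 0.82, SE 0.140), and Mettl7a1 (0.64), the metalloproteinase inhibitor Timp4 (0.63), the acyl-CoA thioesterase Acot11 (0.49) and Ogt (0.75), which encodes the O-GlcNAc transferase. By limma on log2(FPKM + 1), 0 of 14206 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.404. At an unadjusted p under 0.05 there were 1712 genes, 1025 lower and 687 higher in TMAO, where 710 would be expected from 14206 genes with no difference. Under quantile normalization the lower and higher genes numbered 845 and 944. The groups did not overlap in 4197 genes, or 29.5%, where chance gives 10% for a single gene. Genes are not independent, and other splits of the 6 libraries into 3 and 3 gave 585 to 2009 such genes. The 1712 genes became 2437, 1296 and 3365 without vehicle replicates 1, 2 and 3, and 767, 740 and 528 without TMAO replicates 1, 2 and 3. No gene passed the adjusted threshold in any of these fits. The smallest adjusted p by limma was 0.118 without vehicle replicate 1 and 0.0930 without TMAO replicate 2.

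The second comparison concerned the inflammasome and m6A genes named by the study. Nlrp3, the sensor of the inflammasome, was lower in TMAO, at 1.54 ± 0.510 FPKM in vehicle and 0.498 ± 0.163 FPKM in TMAO (SD, n = 3 each), and each vehicle library lay above each TMAO library. The interleukin gene Il1b had 2.20 ± 2.12 FPKM in vehicle and 0.464 ± 0.208 FPKM in TMAO, and Igf2bp2, a reader of m6A-marked RNA, had 1.51 ± 1.9 and 0.244 ± 0.0781 FPKM. Both were lower in each TMAO library than in any vehicle library. Fto, the m6A demethylase, was slightly higher in each TMAO library, at 9.21 ± 1.14 FPKM in vehicle and 10.4 ± 0.241 FPKM in TMAO. The groups overlapped for the adaptor gene Pycard, the protease gene Casp1, Il18 and the pore-forming gasdermin gene Gsdmd.

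The Nlrp3 difference on the log2(FPKM + 1) scale, which understates changes of low genes, was -0.75 (SE 0.190), with a limma p of 0.00721 and an adjusted p of 0.404, and it was -0.61 without vehicle replicate 1. For Fto it was 0.17 (SE 0.116, adjusted p = 0.450 by limma), and 0.076 without vehicle replicate 1. Il1b and Igf2bp2 fell below the expression filter and were not tested by limma. Their log2 differences were -0.94 and -0.76, and -0.44 and -0.19 without vehicle replicate 1, where Il1b had 4.64 FPKM and Igf2bp2 had 3.70 FPKM. Pycard, Casp1, Il18 and Gsdmd had log2 differences of -0.21, -0.12, -0.12 and -0.61 with adjusted p of 0.580, 0.760, 0.767 and 0.481 by limma. Without vehicle replicate 1 these became 0.011, 0.080, 0.12 and -0.097. The exact two-sided permutation p was 0.1 for Nlrp3, Il1b, Fto and Igf2bp2, the smallest that 3 against 3 libraries can give, and 0.2 after Benjamini-Hochberg adjustment over the 8 genes. For Pycard, Casp1, Il18 and Gsdmd the exact permutation p was 0.6, 0.7, 0.8 and 0.4. In the authors' deposited table Nlrp3 was marked as lower, with a log2 fold of -1.63 and a q of 0.0162, and Il1b (-2.24, q of 0.0804) and Igf2bp2 (-2.63, q of 0.0699) were marked as lower too. In the GRCm38 gene annotation, matched by gene ID because the tables give no coordinates, Nlrp3 (ENSMUSG00000032691) lies on chromosome 11 from 59541568 to 59566956 on the plus strand. Fto (ENSMUSG00000055932) lies on chromosome 8 from 91313525 to 91668439, and Igf2bp2 (ENSMUSG00000033581) on chromosome 16 from 22059009 to 22163299. All directions rest on the group labels as given, which the values cannot test.

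**Figure D1:**
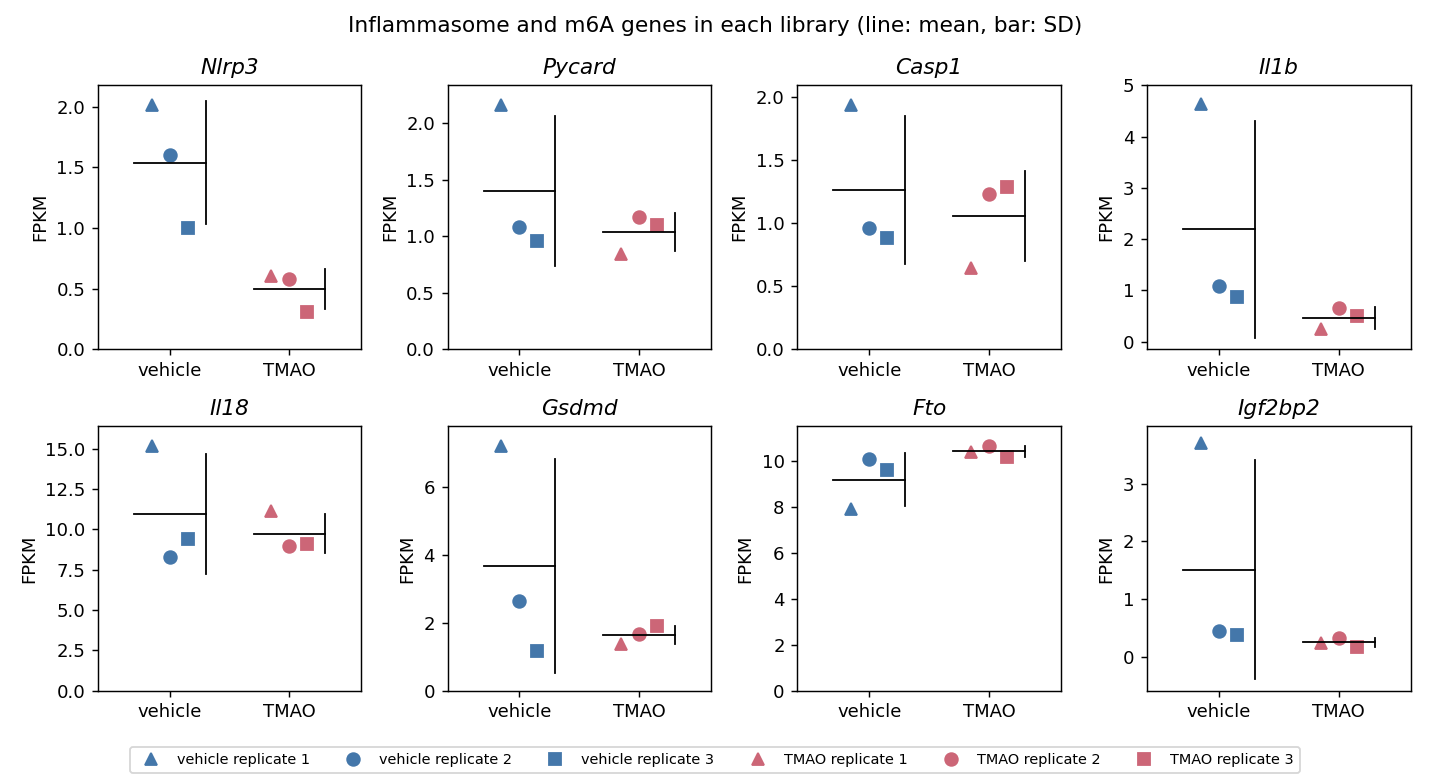
FPKM (vertical axis) of the 8 inflammasome and m6A genes in vehicle and TMAO libraries, 1 point per library, with the group mean as a line and the SD as a bar (n = 3). Nlrp3 lies at 1.0 to 2.02 FPKM in vehicle and 0.311 to 0.606 FPKM in TMAO, and Igf2bp2 reaches 3.70 FPKM in vehicle replicate 1 alone.

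The third comparison asked whether gene lists moved together. Immune lists were lower in TMAO, and so was the heat shock list, a check of sample handling (median -0.89). In the interferon response list 23 of 24 measured members had lower values, with a median log2 difference of -0.63. The guanylate-binding protein genes Gbp3 and Gbp2 went from 3.98 ± 0.296 to 1.56 ± 0.501 FPKM and from 6.93 ± 2.41 to 2.35 ± 0.536 FPKM, and Ifit3 from 10.5 ± 1.51 to 5.34 ± 1.66 FPKM (SD, n = 3). These 3 genes passed when adjusted over the list alone, and 0 passed over all genes. In the cytokine and chemokine list 11 of 12 members were lower (median -1.43). Among them were the chemokine genes Ccl2, at 24.2 ± 25.4 FPKM in vehicle and 2.49 ± 1.81 FPKM in TMAO, and Cxcl1, at 9.69 ± 11.4 and 0.497 ± 0.309 FPKM. Their log2 differences were -2.50 and -2.32, and -1.70 and -1.47 without vehicle replicate 1. The list of Toll-like receptor and NF-kB signalling genes had 19 of 22 members lower (median -0.56), with the lipopolysaccharide co-receptor Cd14 at 66.3 ± 53.5 and 5.19 ± 2.78 FPKM and the adaptor Myd88 at 9.39 ± 3.81 and 3.62 ± 1.0 FPKM. In log2 differences Cd14 and Myd88 were at -2.99 and -1.13, and at -2.32 and -0.85 without vehicle replicate 1. In the list of disease-associated microglia 21 of 22 members were lower (median -1.03), among them Lpl (-1.39), Cd9 (-1.48) and Ccl6 (-2.35), which were at -1.02, -0.94 and -1.56 without vehicle replicate 1. As the libraries held RNA of many cell types, the values of this list and of the other immune lists cannot be assigned to microglia. No member of the cytokine, Toll-like receptor and disease-associated microglia lists passed when adjusted over the list alone (smallest adjusted p 0.0600, 0.130 and 0.128). In the alternative activation list 10 of 11 members were lower (median -0.74), and Socs3, Msr1 and Chil3 passed when adjusted over the list alone, with log2 differences of -2.09, -1.63 and -2.90. With the median without vehicle replicate 1 after each, these medians were -0.43 for interferon response, -1.0 for cytokines, -0.35 for Toll-like receptor signalling, -0.46 for disease-associated microglia and -0.21 for alternative activation, whose median was -1.21 without vehicle replicate 3.

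Stress and housekeeping lists were lower in TMAO as well. The heat shock, ribosomal and immediate early lists were fixed as checks of sample handling and RNA quality, and all 3 moved with the immune lists. The immediate early median was -0.15 without vehicle replicate 1, and the list was then not called. The mitochondrially encoded genes, another of these checks, had all 13 members higher (median 0.13) and were not called. All 14 heat shock genes had lower values (median -0.89, and -0.64 without vehicle replicate 1). The inducible chaperone genes Hspa1a and Hspa1b, near-identical copies whose reads are hard to divide, had 77.4 ± 50.9 and 87.0 ± 49.4 FPKM in vehicle and 10.2 ± 9.22 and 12.5 ± 11.5 FPKM in TMAO, and 10 of the 14 passed when adjusted over the list alone. Among 35 cytosolic ribosomal protein genes 34 were lower (median -0.38, and -0.17 without vehicle replicate 1). The oxidative stress list had 24 of 27 members lower (median -0.64, and -0.23 without vehicle replicate 1), including the haem oxygenase gene Hmox1 at 171 ± 180 and 20.8 ± 14.3 FPKM (log2 difference -2.58, and -1.72 without vehicle replicate 1). The endoplasmic reticulum stress list had 27 of 28 lower (-0.53, and -0.23 without vehicle replicate 1), the lysosome list 28 of 32 (-0.59 and -0.21), the apoptosis and necroptosis list 20 of 23 (-0.43 and -0.21), the antigen presentation list 14 of 15 (-0.70 and -0.26) and the cholesterol and lipid list 24 of 29 (-0.29 and -0.16). Examples were Atf4 (-0.72), Fcgr1 (-0.77), Bax (-0.55), Tap1 (-0.71) and Hmgcs1 (-0.65), at -0.40, -0.58, -0.37, -0.42 and -0.42 without vehicle replicate 1. In these 6 lists and in the ribosomal list no member passed when adjusted over the list alone.

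By camera with a preset correlation of 0.01, 24 of 36 lists were called, 23 lower and 1 higher. With an estimated correlation none was called, with an adjusted p = 0.560 at the lowest, and fry called none either, with a smallest adjusted p of 0.185. For all lists named so far except the immediate early and the mitochondrially encoded genes the adjusted p was 0.560 with an estimated correlation. Without vehicle replicate 1 camera called 17 lists with the preset correlation, none with an estimated correlation (adjusted p = 0.593 at the lowest), and fry called none (smallest adjusted p 0.0681). Of the 23 lower lists 16 were called lower in both fits, and 7 were not. These 7 were the NLRP3 inflammasome list (median -0.42 and -0.14 without vehicle replicate 1, adjusted p = 0.560 with an estimated correlation), complement (-0.78 and -0.33, adjusted p = 0.560 with an estimated correlation), hypoxia and angiogenesis (-0.39 and -0.081, adjusted p = 0.566), immediate early genes (-0.74 and -0.15, adjusted p = 0.664), and the border macrophage, endothelial and fibroblast markers. In the NLRP3 inflammasome list 13 of 14 members were lower, led by Nlrp3 and by Ninj1 at 17.2 ± 16.0 and 4.70 ± 0.151 FPKM (log2 difference -1.31, and -0.62 without vehicle replicate 1), and 0 passed when adjusted over the list alone. All 13 complement members were lower, with C4b at 18.3 ± 4.47 and 11.4 ± 2.17 FPKM. Hypoxia genes included Angpt2 (-2.15, and -1.48 without vehicle replicate 1), and immediate early genes included Jun (-1.60, and -0.89 without it) and, in the other direction, Egr3 (0.72, and 0.51 without it). Without vehicle replicate 3 the medians were -0.65 for the NLRP3 inflammasome list and -1.21 for immediate early genes, and without TMAO replicate 1 immediate early genes were at -0.46 and not called.

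Several lists were not called. The m6A machinery had 15 of 21 members lower and a median of -0.088 (camera adjusted p = 0.347, and -0.034 with an adjusted p = 0.976 without vehicle replicate 1), with Rbmx at 0.30 and Ythdf2 at -0.37. The homeostatic microglia list was split 11 to 11 (median 0.0072, mean -0.13, camera on the higher side, adjusted p = 0.895), with P2ry12 at 3.19 ± 0.762 and 5.18 ± 1.22 FPKM and Fcrls at 22.7 ± 10.3 and 10.2 ± 4.76 FPKM. Oxidative phosphorylation had a median of -0.0034 over 38 genes (adjusted p = 0.895), which was 0.081 under quantile normalization, 0.034 under median scaling and 0.052 rescaled without mitochondrially encoded genes. Camera placed the list on the higher side, and without vehicle replicate 1 it lay on the lower side, with a median of -0.042 and 30 of 38 members lower. Not called either were the mitochondrially encoded genes, with a median of 0.13 (adjusted p = 0.0680). The lists of TMAO and choline metabolism (-0.33, adjusted p = 0.0637) and proliferation (-0.19, adjusted p = 0.114) were not called. With the preset correlation TMAO and choline metabolism was called lower without vehicle replicate 2 (-0.34), vehicle replicate 3 (-0.49) or TMAO replicate 1 (-0.30), and the mitochondrially encoded genes were called higher without vehicle replicate 3 (0.26). Without vehicle replicate 1 their medians were -0.13 and 0.015, not called (adjusted p = 0.665 for both), and with an estimated correlation and all 6 libraries their adjusted p = 0.664 and 0.700. Glycolysis was called lower without TMAO replicate 1 (-0.10, adjusted p = 0.0201), was not called with all 6 libraries (-0.10, adjusted p = 0.0872) and was called lower without vehicle replicate 1 (-0.20, adjusted p = 0.00151, and adjusted p = 0.593 with an estimated correlation). Its lactate transporter Slc16a1 had 15.3 ± 5.19 and 7.73 ± 0.881 FPKM and Ldha had 74.1 ± 5.45 and 53.6 ± 6.67 FPKM.

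**Figure D2:**
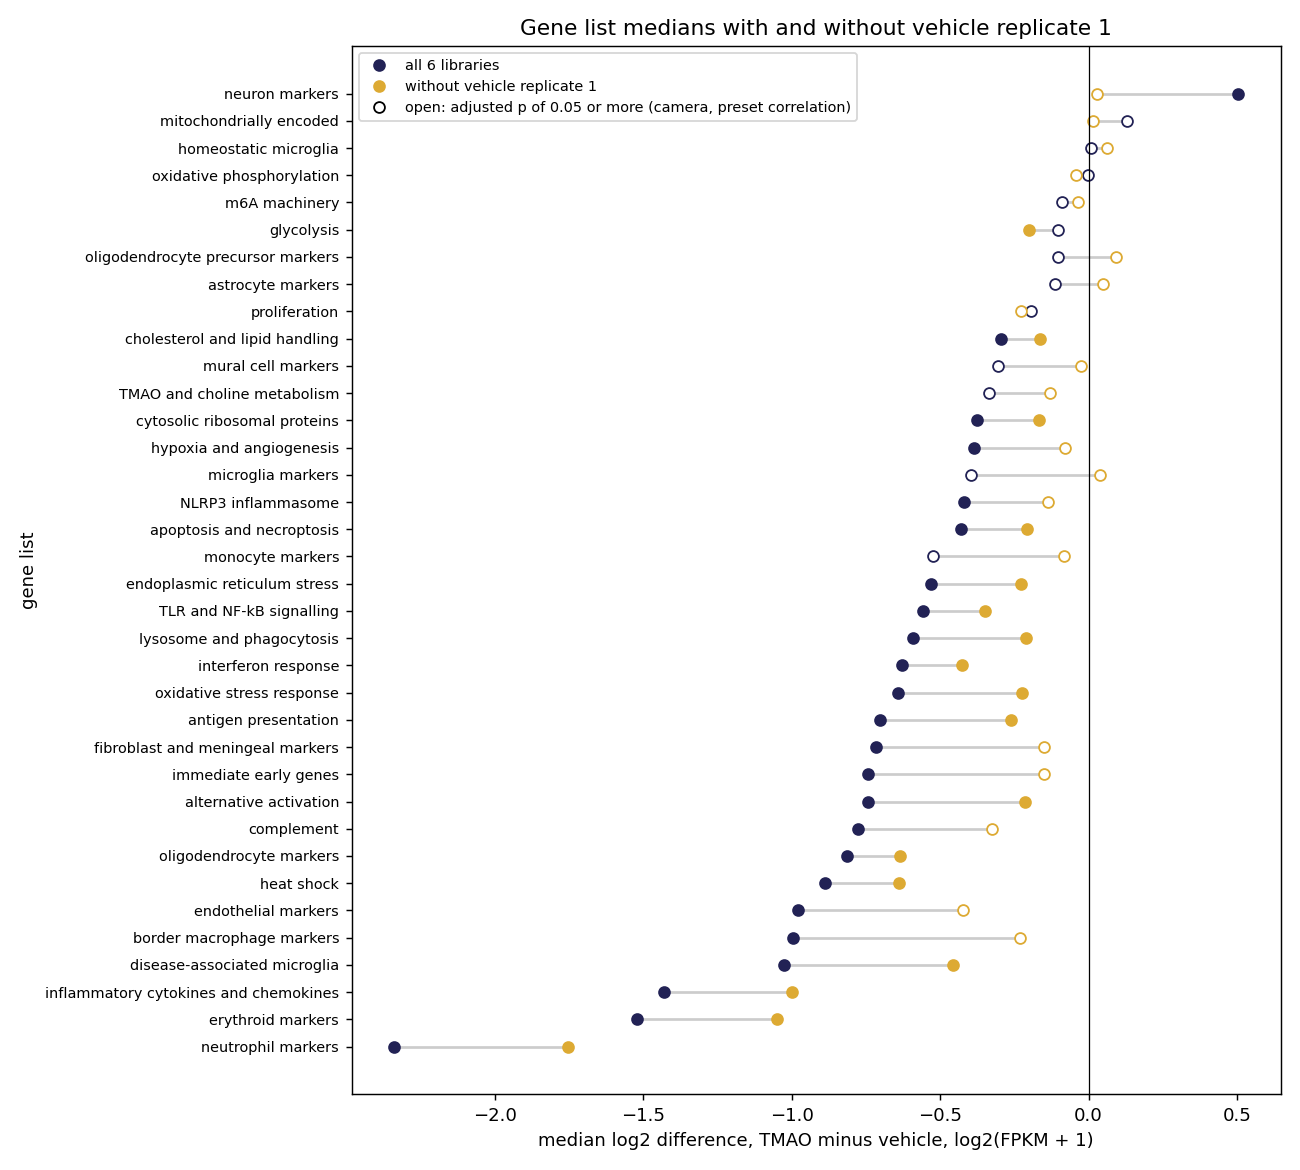
Median log2 difference of each gene list on the log2(FPKM + 1) scale, TMAO minus vehicle (horizontal axis), for the 36 lists tested, with all 6 libraries and without vehicle replicate 1. Filled points passed camera with a preset correlation; the neuron marker median moves from 0.50 to 0.030 and the oligodendrocyte marker median from -0.81 to -0.64.

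The fourth comparison concerned markers of other cell types. Oligodendrocyte markers were lower in TMAO, with all 13 members below vehicle and a median log2 difference of -0.81 (-0.64 without vehicle replicate 1). The myelin genes Mag and Cldn11 went from 38.8 ± 5.32 to 19.9 ± 4.18 FPKM and from 83.1 ± 18.4 to 33.3 ± 9.05 FPKM (SD, n = 3), and 8 of the 13 passed when adjusted over the list alone. The markers summed to 955 ± 126 FPKM in vehicle and 552 ± 140 FPKM in TMAO without overlap. Erythroid markers were lower in 5 of 6 measured members (median -1.52, and -1.05 without vehicle replicate 1), and 5 passed when adjusted over the list alone. Their sum was 389 ± 201 FPKM in vehicle and 135 ± 9.90 FPKM in TMAO without overlap. All 5 measured neutrophil markers were lower (median -2.34), and 4 of the 5 were lower without vehicle replicate 1 (median -1.75). The calprotectin genes were S100a8 at 16.5 ± 11.8 and 1.47 ± 0.457 FPKM and S100a9 at 32.3 ± 29.4 and 2.97 ± 1.28 FPKM, and 3 markers passed when adjusted over the list alone. Over the 12 neutrophil markers the sums overlapped, at 284, 86.3 and 36.4 FPKM in vehicle and 17.6 to 37.0 FPKM in TMAO. The exact two-sided permutation p of the sums was 0.1 for the oligodendrocyte and erythroid markers and 0.2 for the neutrophil markers, and 0.333 and 0.421 after adjustment over the 40 lists. With an estimated correlation the adjusted p = 0.560 for each of these 3 lists.

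Neuron markers were called higher with all 6 libraries, with 11 of 15 members higher and a median of 0.50, which became 0.030 and was not called without vehicle replicate 1 (adjusted p = 0.560 with an estimated correlation). Map2 had 47.4 ± 16.0 and 70.0 ± 9.89 FPKM (log2 difference 0.61, and 0.29 without vehicle replicate 1). Border macrophage, endothelial and fibroblast markers had medians of -1.0, -0.98 and -0.72 and of -0.23, -0.42 and -0.15 without vehicle replicate 1, when none of the 3 was called. With an estimated correlation their adjusted p = 0.560, 0.577 and 0.572. Without vehicle replicate 3 the border macrophage and fibroblast medians were -1.54 and -1.11, and without TMAO replicate 3 the fibroblast markers were at -0.66 and not called. Dab2, Cdh5 and Igfbp2 had log2 differences of -1.79, -2.12 and -1.04, and -1.13, -1.36 and -0.65 without vehicle replicate 1, while the endothelial transporter Slco1a4 had 1.31 and 0.96. Microglia markers were not called (median -0.40, and 0.040 without vehicle replicate 1, adjusted p = 0.444). Their sum was 243 ± 134 FPKM in vehicle and 158 ± 6.98 FPKM in TMAO (exact permutation p = 0.4). Astrocyte markers were not called either (median -0.11, while camera placed the list on the higher side, adjusted p = 0.895, and 0.048 without vehicle replicate 1), with Gfap at 242 ± 120 and 131 ± 27.2 FPKM (log2 difference -0.80, and -0.42 without vehicle replicate 1) and Fgfr3 at 19.2 ± 2.48 and 28.4 ± 3.09 FPKM. Oligodendrocyte precursor markers had a median of -0.10 and a mean of 0.0069 (camera on the lower side, adjusted p = 0.895), with a median of 0.093 without vehicle replicate 1, and Gpr17, a gene of precursors committed to differentiate, had 2.98 ± 1.21 and 7.23 ± 0.921 FPKM and passed when adjusted over the list alone. Monocyte (-0.52) and mural cell (-0.31) markers were not called (adjusted p = 0.444 and 0.140), though mural cell markers were called lower without vehicle replicate 3 (-0.56). Without vehicle replicate 1 the medians were -0.082 and -0.025 (adjusted p = 0.951 for both), and with an estimated correlation and all 6 libraries the adjusted p = 0.80 and 0.691. T and NK cell, B cell, and choroid plexus and ependymal markers had too few members past the filter to be tested, and summed to 13.3 ± 2.25, 12 ± 5.20 and 4.52 ± 0.561 FPKM in TMAO and 10.4 ± 7.81, 11.8 ± 5.50 and 6.20 ± 1.99 FPKM in vehicle.

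**Figure D3:**
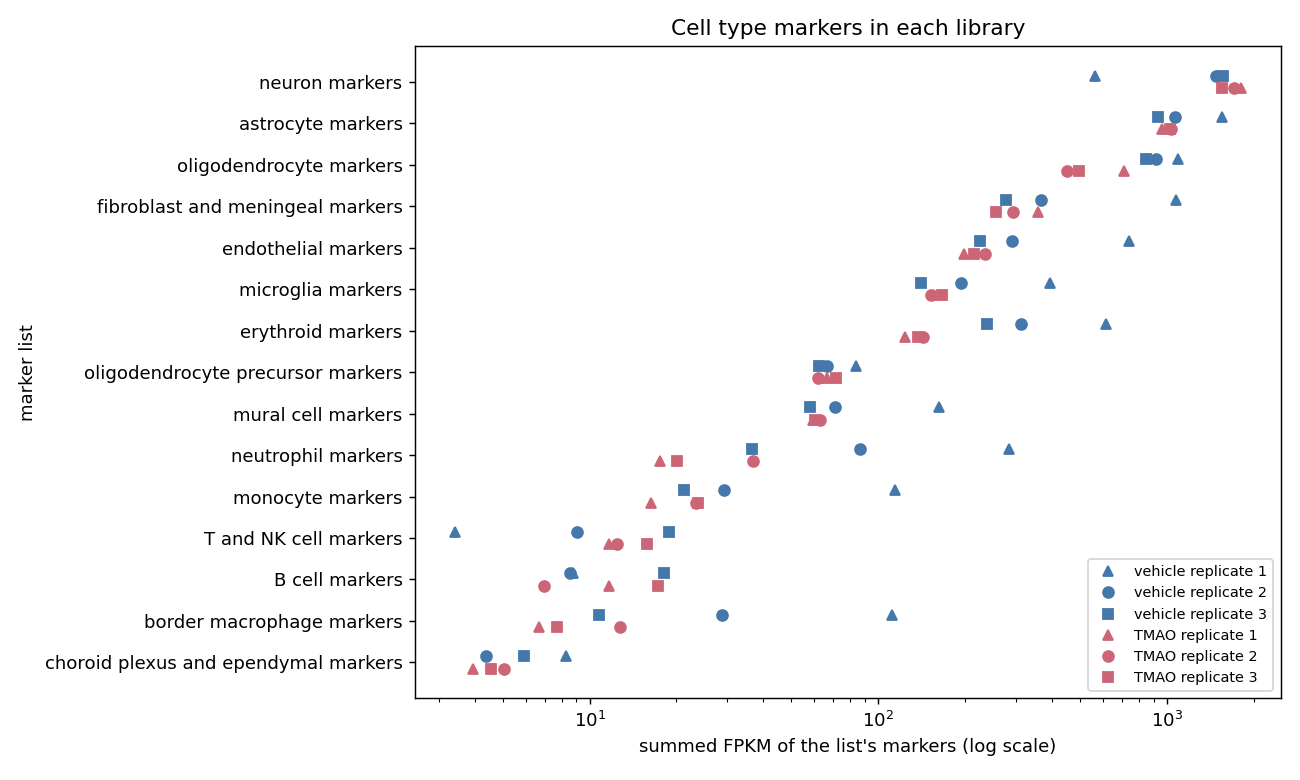
Summed FPKM of each cell type's markers (horizontal axis, log scale) in the 6 libraries, 1 point per library. Oligodendrocyte sums lie at 850 to 1094 FPKM in vehicle and 449 to 712 FPKM in TMAO, and vehicle replicate 1 has the lowest neuron sum at 566 FPKM.

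The authors' deposited table carries its own comparison of the same 6 libraries. It marked immune genes as lower in TMAO, among them 17 of 25 cytokine and chemokine genes, 17 of 25 genes of disease-associated microglia, 16 of 33 interferon response genes and 7 of 21 genes of the NLRP3 inflammasome list, and none of these as higher. The authors' deposited table also marked as lower 7 of 14 heat shock genes, 7 of 8 erythroid, 8 of 12 border macrophage and 7 of 13 endothelial markers, with 1 endothelial marker higher. The authors' deposited table marked 2346 genes, 1861 as lower and 485 as higher in TMAO. All marked genes had a p under 0.05 and at least a 2-fold difference, with q values up to 0.461, and 399 genes in the authors' deposited table had a q under 0.05. Of the 2346 marked genes 808 stayed under 1 FPKM in every library and 966 were among the genes tested here, of which 449 had an unadjusted limma p under 0.05. Vehicle replicate 1 was the highest of the 6 libraries in 1706 of the 1861 genes marked lower. Without vehicle replicate 1, 825 of the 1861 genes marked lower and 365 of the 485 marked higher kept a 2-fold difference of means.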

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

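The fits without robust estimation, with array weights and with FPKM rescaled without mitochondrially encoded genes, and the count of deposited marks without vehicle replicate 1, were chosen after seeing the data. No gene passed the adjusted threshold of 0.05 under any of the 17 alternative fits, by limma, nor at 0.10 with all 6 libraries, and the smallest adjusted p ranged from 0.0930 to 0.663. The 1712 genes at an unadjusted p under 0.05 became 987 under the stricter filter, which tested 7503 genes, and 1074 with array weights, and ran from 528 to 3365 over fits that left out 1 library. Lists called by camera numbered 17 to 27 when 1 library was left out, 17 of 27 tested under the stricter filter, 24 to 26 under the other scalings, filter, trend and pseudocount, and 19 with array weights. Array weights called none of the 7 lower lists that were not called without vehicle replicate 1, the NLRP3 inflammasome list among them, and called glycolysis and oxidative phosphorylation lower (-0.17 and -0.12). Called lists numbered 0 with an estimated correlation, 0 by fry and 0 by the mixed test of fry. Under the stricter filter the antigen presentation and hypoxia lists were not called (adjusted p of 0.0656 and 0.192). The mitochondrially encoded genes were called higher under that filter and without a trend (0.0448 and 0.0300). The neutrophil median was -0.97 without the low-expression filter and -1.06 with array weights, and the interferon median was -0.99 with a pseudocount of 0.1. Without the low-expression filter the proliferation and monocyte lists were called, and rescaling without mitochondrially encoded genes called those genes higher, with a median of 0.19 and an adjusted p of 0.0499. Cell type lists called numbered 7, against 4 under the stricter filter, which tested 7, 4 with array weights and 3 to 8 when 1 library was left out. With 1 library left out the log2 difference ran from -0.24 to 0.080 for Casp1, from -0.34 to 0.011 for Pycard and from -0.28 to 0.12 for Il18, each time highest without vehicle replicate 1. Casp1 was also above 0 without TMAO replicate 1, at 0.028. With array weights Casp1 was at 0.083 and Gsdmd at 0.026, against negative values with all 6 libraries. For array weights the cause was not tested. The number of study genes without overlap was 4 or 5 under median scaling, rescaling without mitochondrially encoded genes and with 1 library left out. For the title block, the differences between same-numbered libraries all had the same sign in 4 study genes. In the authors' deposited table, 399 genes had a q under 0.05, 369 of them with a 2-fold change, and 3765 had a p under 0.05, against 2346 marked. Of these, 1190 kept a 2-fold difference without vehicle replicate 1.

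With the title numbers as a replicate block 0 genes passed, 1259 had an unadjusted p under 0.05, and 25 lists were called, 7 of them of cell types. Over the 4 libraries that share a description number the block gave 0, 1461, 29 and 10. By camera with the preset correlation both blocks called TMAO and choline metabolism lower (adjusted p of 0.0468 and 0.0494). The block of shared description numbers also called mitochondrially encoded genes higher (0.0494) and microglia, monocyte and mural cell markers lower (0.0149, 0.0188 and 0.00754). The block fits were not run with an estimated correlation, under which none was called with all 6 libraries. Deviations of same-numbered libraries from their group means correlated at -0.22, -0.06 and -0.02, so the numbers were not taken to pair the samples. DESeq2, voom and a fit of FPKM beside counts were not run, because the tables hold no counts. FPKM without counts leave the counting error of low genes unknown.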

Other observations

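Gene sets drawn from the pathway annotation in the deposited tables added groups not in the fixed lists. Proteasome genes (42) had a median log2 difference of -0.34 and -0.23 without vehicle replicate 1, and genes of the Jak-STAT signalling pathway (86) had -0.27 and -0.14. Genes of the glutamatergic synapse (99) had 0.22 and 0.05. By camera with a preset correlation 76 of 279 sets were called lower and 11 higher in TMAO, and 47 and 2 of these were also called without vehicle replicate 1. With an estimated correlation none was called, with an adjusted p = 0.720 at the lowest. These sets were chosen after seeing the data.

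The fits without vehicle replicate 1, the fit with median scaling and the splits of the 6 libraries by genes at an adjusted p under 0.05 were planned, and the splits of the 5 libraries were set up before their results were seen. The other tests in this part, and the readings of the planned fits, were chosen after the results were seen. With 3 against 3 libraries, and with 2 against 3, there are 10 splits, too few for a share under 0.05. For genes at an adjusted p under 0.05 the real grouping gave 0 and the highest other split 1, and with a real count of 0 each of the 10 splits gives as many by construction. At an unadjusted p under 0.05 the real grouping gave 1712 genes and the highest other split 480, so that 1 of 10 gave as many. For lists called by camera with a preset correlation the real grouping gave 24 and the highest other split 31, and 4 of 10 splits, the real one included, gave as many. The others, with 25, 27 and 31 lists, each put vehicle replicates 1 and 2 with 1 TMAO library and vehicle replicate 3 on the other side. List calls were thus no fewer with vehicle replicate 3 counted as TMAO, though these splits gave 235, 480 and 336 genes at an unadjusted limma p under 0.05. Without vehicle replicate 1 there were 10 splits of 5 libraries into 2 and 3. Of these 3, the real one included, called as many lists as the real 17 (highest other 22). Only the real one gave as many genes at an unadjusted p under 0.05 as the real 2437 (highest other 1165).

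Vehicle replicate 1 stood apart from the other 5 libraries. A lower share of neuron RNA alone would raise the markers of all other cell types alike, but their list medians in vehicle replicate 1 over the other 5 differed by 1.93 on the log2 scale, from oligodendrocyte precursors (0.44) to border macrophages (2.37), against median absolute deviations of 0.381 together. FPKM divide by depth, so a difference in depth would leave the abundant neuron markers near 0, and their median was -1.12, with a median absolute deviation of 0.362. A swap with a TMAO library could leave a TMAO library closer to vehicle replicates 2 and 3 than to its own group, and 0 did. Vehicle replicate 3 itself correlated with the TMAO libraries at 0.975 to 0.981 and with vehicle replicate 2 at 0.977. A vehicle library among the TMAO libraries might therefore go unseen, and this check cannot exclude a swap. A single wrong label, another brain region or injury, and more vascular and immune cells in that piece of tissue may each be the source, and no test here bears on them.

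Nlrp3 RNA and immune lists were lower in TMAO, while the series title states the other direction for the inflammasome of microglia. The values here are RNA of mixed brain cells, and the labels describe no stroke surgery, so they do not test that statement. An exchange of the 2 groups' labels, which would turn every difference, was not tested and stays open. Without vehicle replicate 1, 15 lower lists were still called with medians below 0 by more than their members' median absolute deviation (interferon response -0.43, 24 of 24 lower). By camera with an estimated correlation none was called (adjusted p = 0.593 at the lowest). That deviation is taken over genes that move together, and 3 of 10 splits without vehicle replicate 1, the real one included, called as many lists. For disease-associated microglia, vehicle replicate 3 (summed 946 FPKM) lay among the TMAO libraries (869 to 1008 FPKM). These calls therefore cannot tell a shift of the whole group from differences between single libraries. For the other 8 lower lists, the NLRP3 inflammasome list among them, vehicle replicate 1 and the diet cannot be told apart, because their medians were below 0 without it but not called or within that spread. For Nlrp3 vehicle replicate 1 alone (mean of vehicle replicates 2 and 3 at 2.61 times the TMAO mean) stays open, because Nlrp3 was near the floor in TMAO. For that reason the ratio of Nlrp3 to the microglia markers, 2.15 times higher in vehicle, cannot exclude fewer microglia. Without vehicle replicate 1 the markers themselves had a median log2 difference of 0.040. Their sums overlapped, at 194 and 140 FPKM in vehicle and 152 to 166 FPKM in TMAO. Among those libraries this argues against fewer microglia, which stays open once vehicle replicate 1 (394 FPKM) is included. For the neutrophil and erythroid lists 1 blood source (ratio of S100a8 to Hbb-bs differing 8.03-fold) stays open, because S100a8 was near the floor in TMAO, below the same limit of 5 FPKM. Sample handling and the diet cannot be told apart, because the heat shock list, a check of handling, was lower in TMAO too (-0.89, median absolute deviation 0.435), so that an effect of the diet is a hypothesis.

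Oligodendrocyte markers were lower in TMAO. The scaling of FPKM is argued against, since the median was -0.78 under median scaling, and so is dilution by RNA of another cell type, since the astrocyte median lay 0.70 above the oligodendrocyte median, against median absolute deviations of 0.534 together. All 13 members were lower, as they would be with less white matter in the piece taken and also if oligodendrocytes made less of these RNAs, so these cannot be told apart without a record of the dissection. Whether the diet lowered myelin gene expression may be asked of these data only as a hypothesis.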
